A study of Mus musculus with 4 samples.

How the data were processed

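RNA from mouse hearts at embryonic day 9.5 was hybridised to 4 two-colour Agilent arrays on 1 slide, each with a pool of 3 mutant and a pool of 3 control hearts, and the labels call these 4 biological replicates. The authors deposited scanner output for each array and a table of normalized values. Per the file headers, the scanner files hold spot mean and background intensity for Cy3 and Cy5 from Agilent Feature Extraction 11.5.1.1, while the submitters' processing notes name Agilent Feature Extraction 8.5.1.1. The files also hold processed intensity signals, which the software had background-subtracted and dye-normalized, and their ratio as log10 of Cy5 over Cy3, per the file headers. The deposited table gives log2 ratios in columns named mutant against wild type, by a normalization method not given in the sources used here. Its column medians were -0.027, -0.017, 0.021 and 0.025. Its rows were matched to probes by probe name, because its feature numbers did not match the scanner files, and 153 of its 43173 rows were controls.

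The direction of the ratios rests on a conflict between sources. The labels give mutant RNA as Cy5 on every array, and the design fixed before the data were examined assumed this. Against the scanner's log2 Cy5 over Cy3 on probes with both mean signals above 2000, the deposited columns had slopes of 1.03, 1.01, -0.99 and -1.01, as they would if the authors treated arrays 3 and 4 as dye-swapped. The main result departs from the fixed design by turning the sign of these 2 arrays. This choice was made after the Hdac3 values had been seen under both signs. A dye effect cancels in the mean of 2 arrays of each orientation. The fit with all arrays as labelled has the orientation of the fixed design and became an alternative once arrays 3 and 4 were turned. A fit with a dye term and a fit of arrays 1 and 2 only were added after seeing the data.

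In R 4.3.3 with limma 3.58.1, the background was corrected with normexp (offset 50) on the mean and local background intensities, and each array was normalized by loess with the 1377 control spots at weight 0. Control spots and spots with non-uniformity or population outlier flags (308 to 407 per array) were then left out, spots of one probe were averaged, and no spot was saturated. Of 39429 probes, 25483 were well above background on all 4 arrays in the mutant or in the control channel and were kept. The offset draws the log ratios of dim probes towards 0. Probe names came from an mm9 design, and 27508 probes were named by accession through a RefSeq table of assembly GRCm38.p6, used for names only, 404 through an older symbol, and the others kept the name in the files. A gene was represented by its brightest probe, which gave 19605 genes, of which 4676 had several probes. Of the 77 genes picked by the rule for naming, 16 had several probes past the filter and 1, Wnt4, had such a probe of opposite sign. Probes below the filter also read opposite to the probe used for Epb42 (0.11), Erg (-0.01), Fgf1 (0.12) and Cldn7 (-0.16).

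The log2 ratios were tested against 0 with lmFit and eBayes, with Benjamini-Hochberg adjustment and a threshold of 0.05. An exact sign test of 4 pairs cannot give a two-sided p below 0.125. Gene lists with at least 5 measured members (41 lists, 1031 of 1034 genes on the array), fixed before the data were examined, were tested with camera at a preset correlation of 0.01, adjusted over the lists. This preset treats the genes of a list as nearly independent, so the p-value is too small for a list whose genes move together. The genes named were Hdac3, Tbx5, Nkx2-5 and Tgfb1, then the 12 leading genes in each direction, which by the rule were those of smallest unadjusted p with one sign on all 4 arrays and an ordinary symbol, since none passed the threshold, and up to 4 members of smallest p from each list described; some genes that the rule picked are not reported here. Levels per channel are percentiles after loess and quantile normalization of average intensity. Between 66.6% and 71.2% of probes were well above background per channel, and the spike-in controls had a slope of 0.861 to 0.884 against their expected log ratios, with r of 0.993 to 0.995.

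The steps were tested on simulated data. Simulated mutant against control ratios of 19605 genes were given each gene's spread over the 4 arrays after eBayes shrinkage, and 200 genes were changed. The test called 74% of genes changed by 0.5 on the log2 scale, 96% of those changed by 1 and 100% of those changed by 1.5. There were 12 false calls. In simulated ratios with the second heart field list shifted by 0.18, camera called that list and 0 others. The simulation drew genes independently and held no dye effect. Shrunken variances differ less between genes than those of the real arrays, so the shares called can overstate the power of the test. In the real data Lum had a mean log2 ratio of -0.81 and an adjusted p of 0.248 (limma). A count of 0 genes therefore does not exclude changes of these sizes. The alternatives chosen before the data were examined varied the background correction, its offset, the signals used, the normalization, the scaling between arrays, the filter on dim probes, the flagged spots, the summary of several probes, the variance model, array weights, each replicate, the pairing, the authors' table, a GC trend, the threshold and the gene list test.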

Results

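Gene expression was measured in microdissected mouse hearts at embryonic day 9.5, in embryos whose Hdac3 gene, which encodes a class I histone deacetylase, was targeted with a Cre recombinase driven from the Nkx2-5 locus in cardiac progenitors. Control hearts came from littermates with the floxed gene but no stated Cre. The design therefore does not separate loss of Hdac3 from the presence of Cre at the Nkx2-5 locus. There were 4 two-colour arrays, each of which paired RNA pooled from 3 mutant hearts with RNA pooled from 3 control hearts, so n = 4 pairs of pools. Each array held 44397 spots, and between 66.6% and 71.2% of the probes were well above background in a given channel. The number of arrays limits the precision of every value. The labels place the mutant RNA in Cy5 on all 4 arrays, whereas the columns of the authors' deposited table, named as mutant against wild type, run with Cy5 over Cy3 on arrays 1 and 2 (r = 0.932 and r = 0.940 over bright probes) and against it on arrays 3 and 4 (r = -0.992 and r = -0.951). All mutant over control values given here follow the authors' table, so their direction is likely, on the basis of its column names, and not settled by the labels.

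The signals of heart muscle and pluripotency genes were fixed for reporting as percentiles of all probes in each channel. The sarcomere genes, which encode the contractile apparatus, had median levels at the 95.9th to 96.9th percentile of probes in the mutant channels and the 96.0th to 96.4th in the control channels (35 genes). Cardiac actin, Actc1, lay at or above the 99.97th percentile in all channels, and Nkx2-5, a cardiac transcription factor, lay between the 94.4th and the 96.0th. The pluripotency genes had medians between the 49.6th and the 53.7th percentile (27 genes), and Pou5f1, a core pluripotency factor, was not well above background in either channel of any array. Other pluripotency genes were well above background in both channels of all 4 arrays, Nanog at the 59.8th to 63.9th percentile, Utf1 at the 70.1st to 75.6th and Zfp42 at the 31.2nd to 42.1st. The descriptions of replicates 2 to 4 name embryonic stem cells, while their titles, sources and genotypes name hearts. In replicates 2 to 4 the sarcomere medians lay between the 95.96th and the 96.85th percentile, near those of replicate 1 (95.9 and 96.1). For these genes as a set, the levels argue against embryonic stem cells as the only source of RNA in replicates 2 to 4. Levels of different probes are not comparable with each other, no reference sample was measured and no test was run. The percentiles therefore do not measure how far each pool was heart.

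The Hdac3 transcript was lower in the mutant pools on all 4 arrays, with log2 ratios of -0.22, -0.48, -0.45 and -1.097. The mean was -0.56 ± 0.38 (SD, n = 4), a ratio of 0.677, and it did not pass the test across all genes (limma, adjusted p = 0.595). The single Hdac3 probe lies on chromosome 18 from 38096655 to 38096714 in mm9. Its place relative to the floxed exons is not given in the sources used here, and a probe outside the deleted part would not measure the deletion. With all arrays read as labelled, the mean became 0.21. The signs were chosen after Hdac3 had been seen under both readings, so its agreement on 4 arrays tests neither the signs nor the deletion.

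**Figure D1:**
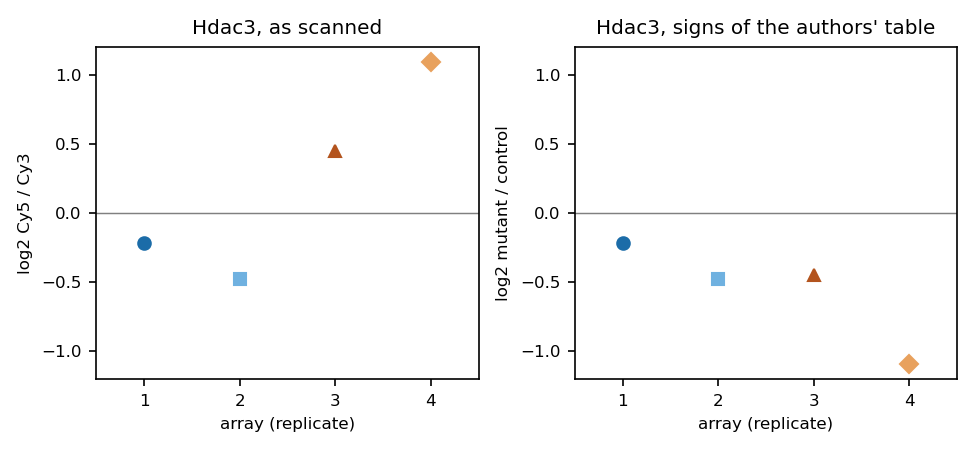
Log2 ratios of the Hdac3 probe on each of the 4 arrays (x axis, replicate), at left as Cy5 over Cy3 and at right as mutant over control with the signs of the authors' table. As scanned, arrays 1 and 2 lie below 0 (-0.22 and -0.48) and arrays 3 and 4 above it (0.45 and 1.097), and all 4 lie below 0 once turned.

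The 3 other genes fixed for reporting were nearer to 0 than Hdac3. Tbx5, a T-box factor of the atria and left ventricle, had a log2 ratio of 0.20 ± 0.15 (SD, n = 4; 0.129 without replicate 2) and was above 0 on 4 arrays. Tgfb1, which encodes a TGF-β ligand, had a ratio of 0.15 ± 0.20 (0.0707 without replicate 3), and Nkx2-5 one of -0.08 ± 0.36 (-0.181 to 0.0884 over leaving out each replicate), each with 2 arrays on either side of 0. Both signs turned with all arrays read as labelled, to -0.0403 for Tgfb1 and 0.249 for Nkx2-5. None of the 3 passed the test (adjusted p = 0.623, 0.711 and 0.891).

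The comparison of all genes asked which transcripts differ between the pools labelled Hdac3 mutant and control. The genes of smallest p were higher or lower on all 4 arrays but none passed the threshold, so the genes named here are the leading ones of a list that holds no call. Of the 12 leading genes lower in the mutant pools, Lum, which encodes the matrix proteoglycan lumican, had the mean farthest from 0 with the authors' signs, a log2 ratio of -0.81 ± 0.17 (SD, n = 4; adjusted p = 0.248), and a mean of -0.146 with all arrays read as labelled. Acyp2, an acylphosphatase, had a ratio of -0.74 ± 0.13 (adjusted p = 0.248), and its other probe read -0.19. Further genes lower on every array were Trib2 (-0.62, other probe -0.07), Bhlhb9 (-0.58), Epb42, an erythrocyte membrane protein (-0.57), Kat2b, a histone acetyltransferase (-0.55), Phox2a, an autonomic neuron factor (-0.55), Plbd1 (-0.50), Ndrg4 (-0.49), Arhgap18 (-0.47), Tarsl2 (-0.45) and Lrrc42 (-0.44). Read as labelled, the means of these 12 ran from -0.146 to 0.206.

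Of the 12 leading genes higher in the mutant pools, Tnnc2, fast skeletal troponin C, had the largest mean, with a log2 ratio of 0.90 ± 0.43 (SD, n = 4). Pvalb, the calcium buffer parvalbumin, had a ratio of 0.73 ± 0.28, Tnnt1, slow skeletal troponin T, 0.59 ± 0.16, and Kcna5, an atrial potassium channel, 0.63 ± 0.14, with its other probe at 0.20. Lmnb1, a nuclear lamin, had a ratio of 0.71, Igf2os, a transcript antisense to Igf2, 0.68, Hmga2-ps1, 0.65, Sbk3, 0.58, Trabd2b, 0.48 (other probes 0.37 and 0.16), Smoc2, 0.46, Ly6h, 0.45 (other probe 0.12), and Inha, an inhibin subunit, 0.42. Their adjusted p-values ran from 0.248 for Igf2os to 0.592 for Tnnc2, and read as labelled their means ran from -0.190 to 0.0854. Hmga2-ps1 is named as a pseudogene, and its probe may not separate it from Hmga2.

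**Figure D2:**
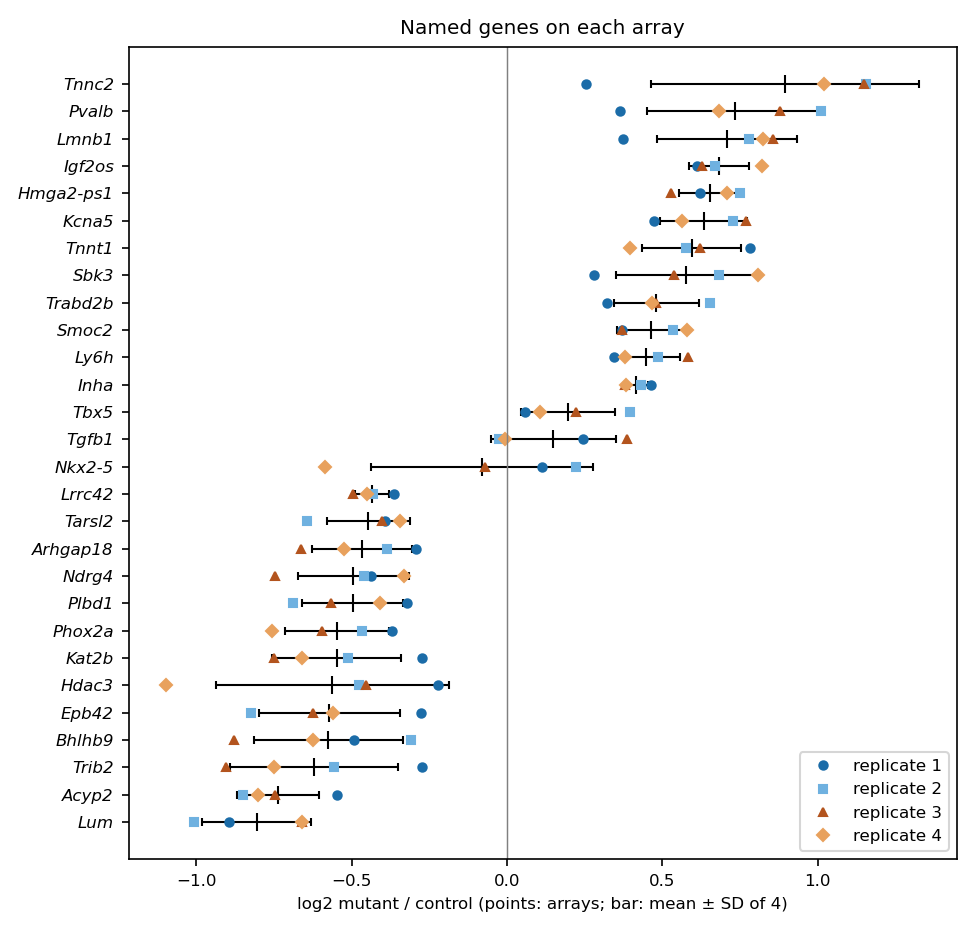
Log2 mutant over control ratio (x axis) of the 4 genes reported whatever their values and the 12 leading genes in each direction (y axis), with a point for each of the 4 arrays and the mean ± SD as a bar. Lum (-0.81) and Tnnc2 (0.90) have the means farthest from 0, and no gene shown passed the threshold.

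With limma, 0 of 19605 genes were higher and 0 were lower in the mutant pools at an adjusted p below 0.05, and also at 0.10, and the smallest adjusted p was 0.248. At an unadjusted p below 0.05 there were 761 genes higher and 809 lower, where 980 in all would be expected by chance. Genes that move together widen the spread around that number, so setting the counts against it is not a test. These counts depended on the processing, with 594 higher and 261 lower under median centring in place of loess and 328 and 326 with no replicate block, both below 980 in all. Other settings raised them, to 1090 higher and 1401 lower with array weights and to 1344 and 1498 with a dye term. With all arrays read as labelled, 99 genes were higher and 9 lower in Cy5 than in Cy3, and without replicate 1, 5 genes were higher and 0 lower.

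Genes of primitive red blood cells were lower as a group in the mutant pools. Of 28 measured members, 25 had a mean below 0 and 3 above, with a median log2 ratio of -0.24, and the list passed the test (limma camera with a preset correlation, adjusted p = 3.16e-09) but not with an estimated correlation (adjusted p = 0.510). Epb42 was at -0.57 ± 0.23 (SD, n = 4), Rhag, an erythrocyte ammonium transporter, at -0.45 ± 0.22 and Trim10 at -0.42 ± 0.21. The median differed between the pairs of pools, at 0.00, -0.55, -0.13 and -0.18 on arrays 1 to 4. No member passed over all genes, and 3 passed adjusted over the list alone. Without replicate 2 the median was -0.16, and with all arrays read as labelled it was -0.066 and did not pass (adjusted p = 0.607).

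Genes of the second heart field, the progenitor pool that adds cells to both poles of the heart tube, were higher as a group in the mutant pools. The median log2 ratio was 0.18, 18 of 23 measured members had a mean above 0, and the median was above 0 on every array (0.17, 0.32, 0.11 and 0.13; camera adjusted p = 2.70e-05; adjusted p = 0.510 with an estimated correlation, which did not pass). The estimated correlation of this list was 0.007, below the preset 0.01, so a higher correlation is not why the call was lost. With all arrays read as labelled the median was 0.0094 and did not pass (adjusted p = 0.562). Fst, the activin antagonist follistatin, was at 0.72 ± 0.37 (SD, n = 4), Tbx1, a T-box factor of the pharyngeal region, at 0.66 ± 0.42 and Nr2f1 at 0.32 ± 0.23. Markers of myocardium of the atrioventricular canal and outflow tract were higher as well, with a median of 0.12 and 11 of 16 members above 0 (adjusted p = 0.0299; adjusted p = 0.510 with an estimated correlation). This median turned to -0.0759 with all arrays read as labelled (adjusted p = 0.951). In this list Tbx3 was at 0.34 ± 0.33 (SD, n = 4; 0.187 without replicate 3), Shox2, a factor of the sinus node, at 0.29, Tbx2 at 0.28 (0.189 without replicate 3) and Wnt4 at 0.22, although the other Wnt4 probe read -0.07. No member of either list passed over all genes, and adjusted over the list alone 2 passed in the former and 0 in the latter. The atrioventricular canal list also lost its call in 6 of 18 other settings, with an adjusted p of 0.146 without replicate 2, and with a dye term (0.0781).

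Markers of liver and foregut endoderm, tissues next to the heart, moved in the same direction as the second heart field genes. Lists of other tissues in or near the heart did not pass (camera). Their medians were -0.13 for the epicardium, -0.04 for the neural tube, 0.003 for the neural crest and 0.11 for skeletal muscle and somites. The list of liver bud, septum transversum and visceral endoderm genes had a median of 0.18, with 11 of 13 measured members above 0 (camera adjusted p = 0.00039; adjusted p = 0.510 with an estimated correlation). This list was fixed with 23 members. As labelled, the liver median was 0.0913 and did not pass (adjusted p = 0.151). Of its members, Apoc2 was at 0.52 ± 0.23 (SD, n = 4), Vil1 at 0.50 ± 0.31, Ttr, the thyroid hormone carrier transthyretin, at 0.26 ± 0.15 and Apom at 0.24 ± 0.10. In the pharyngeal and foregut endoderm list, fixed with 22 members, all 11 measured members were above 0. Their median was 0.17 (camera adjusted p = 0.0020; adjusted p = 0.510 with an estimated correlation). Spink1 was at 0.75 ± 0.55, Krt18, an epithelial keratin, at 0.28 ± 0.33, Cldn7 at 0.19 ± 0.15 and Foxa2, an endodermal transcription factor, at 0.18 ± 0.14. The median of the endoderm list turned to -0.126 with all arrays read as labelled (adjusted p = 0.151). Its median with the authors' signs was -0.07 on array 1 and 0.13, 0.31 and 0.25 on arrays 2 to 4. Foxa2 was well above background in the control channel on 3 of 4 arrays. It is also a member of the liver list, whose median is the mean of Foxa2. Adjusted over the list alone, 2 members of the liver list and 0 of the endoderm list passed. The endoderm list also lost its call with array weights (adjusted p = 0.0940) and without replicate 4 (0.0548), and its median was 0.114 without replicate 3.

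Endocardial and endothelial genes were higher as a group, with a median log2 ratio of 0.12 and 25 of 30 members above 0 (camera adjusted p = 0.0020; adjusted p = 0.510 with an estimated correlation, which did not pass). Erg, an endothelial ETS factor, was at 0.50 ± 0.17 (SD, n = 4), Nfatc1, a factor of the valve endocardium, at 0.32 ± 0.12 and Cldn5, an endothelial junction protein, at 0.22 ± 0.04, whereas Emcn, endomucin, was at -0.23 ± 0.17. Genes of WNT signalling had a median of 0.10, with 22 of 31 members above 0 (adjusted p = 0.0279; adjusted p = 0.579 with an estimated correlation), and included Wnt2 at 0.58 ± 0.48 (SD, n = 4; 0.362 without replicate 3), Fzd7 at 0.41 (0.27 as the mean of its probes), Fzd10 at 0.37 and Wnt5a at -0.29. Genes of FGF and MAPK signalling had a median of 0.07, with 16 of 23 above 0 (adjusted p = 0.0286; adjusted p = 0.510 with an estimated correlation), and included the feedback regulators Dusp6 at 0.45 and Spry4 at 0.20, the target Etv5 at 0.37 and the ligand Fgf1 at -0.37. Adjusted over the list alone, 1 endocardial gene and 0 genes of the WNT and FGF lists passed. All 3 medians turned with all arrays read as labelled, to -0.0471 for the endocardium, -0.0604 for the WNT and -0.0465 for the FGF list, and none passed. The FGF list passed in 9 of 18 other settings, with a median of 0.043 and an adjusted p of 0.146 without replicate 4, and the WNT list in 13 of 18, with a median of 0.062 and an adjusted p of 0.0967 without replicate 3, and not with a dye term (0.0629).

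Cell cycle genes were lower as a group by a small amount, with a median log2 ratio of -0.06 and 33 of 40 members below 0 (camera adjusted p = 0.0047; adjusted p = 0.510 with an estimated correlation). Cdc25c, a mitotic phosphatase, was at -0.32 ± 0.20 (SD, n = 4), Mcm4, a replication helicase subunit, at -0.24 ± 0.20, the proliferation marker Mki67 at -0.23 ± 0.28 (-0.116 without replicate 2) and E2f2 at -0.19 ± 0.16. No member passed adjusted over the list alone. With median centring in place of loess the median was 0.04 and the call was lost, but this moved the median of all genes to 0.066, above that of the list, and with all arrays read as labelled the median was -0.0016.

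**Figure D3:**
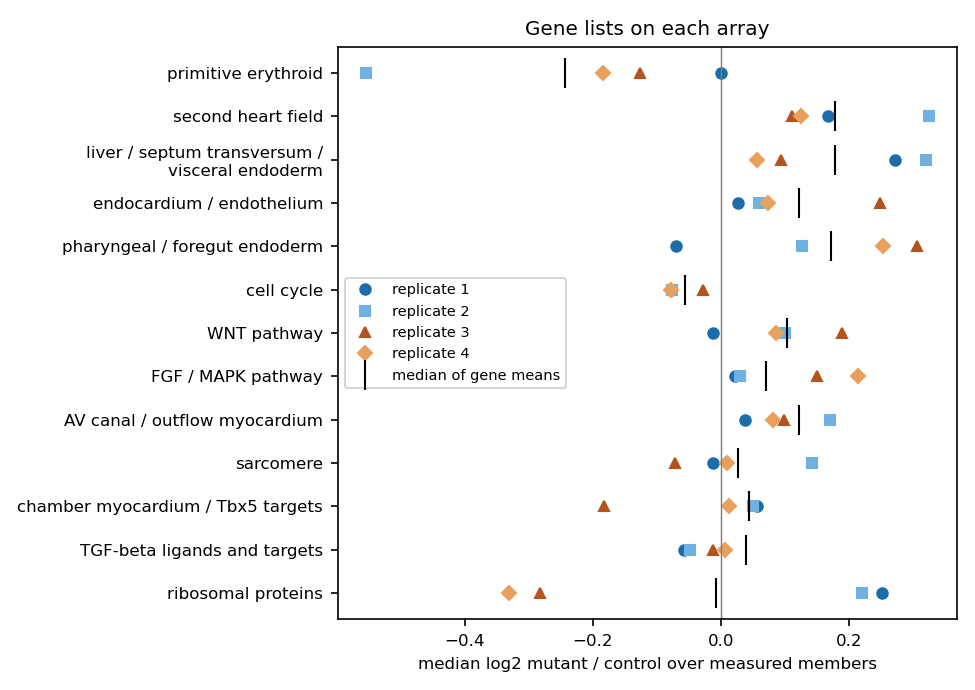
Median log2 mutant over control ratio (x axis) over the measured members of 13 gene lists (y axis), with a point for each of the 4 arrays and a bar for the median of the gene means. The second heart field medians lie above 0 on every array (0.11 to 0.32), whereas the ribosomal protein medians lie at 0.25 and 0.22 on arrays 1 and 2 and at -0.28 and -0.33 on arrays 3 and 4.

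The working myocardium did not pass as a group. The sarcomere list had a median log2 ratio of 0.03 (33 members, camera adjusted p = 0.347), with Tcap, titin cap, at 0.39 ± 0.39 (SD, n = 4; 0.221 without replicate 3) and Xirp1 at 0.22 ± 0.19 (0.143 without replicate 3). The list of chamber myocardium and Tbx5 target genes had a median of 0.04 (22 members, adjusted p = 0.734), with Kcna5 at 0.63 and Smpx, a striated muscle protein, at -0.34 ± 0.09, and 2 members passed adjusted over the list alone. Cardiac transcription factors had a median of 0.00 (31 members, adjusted p = 0.321), with Tbx1 at 0.66 and Hey2, a ventricular factor, at -0.44 ± 0.38. TGF-β ligands and targets had a median of 0.04 (28 members, adjusted p = 0.736), with Tgfbi at -0.36 ± 0.26 (-0.234 without replicate 2) and Smad6 at 0.28 ± 0.15. Histone deacetylases and the Hdac3 corepressor complex had a median of 0.01 (28 members, adjusted p = 0.734), with Tbl1x, a corepressor subunit, at 0.32 ± 0.17 and Hdac11 at -0.24 ± 0.10. The sign of each of these 5 medians turned in at least 1 other setting. The 4 lists other than the chamber list had no member that passed adjusted over the list alone.

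In all, 9 of 41 gene lists passed the test, 7 higher and 2 lower in the mutant pools. Some of these lists share members, so they are not independent results. Foxa2 was in the liver and foregut endoderm lists, and Wnt4, Wnt11 and Rspo3 in the atrioventricular canal and WNT lists. The second heart field list shared Fgf8 and Fgf10 with the FGF list and Dkk1 with the WNT list. With an estimated correlation 0 passed, and 0 passed with fry, which tests whether the genes of a list move one way. The estimates were 0.47 for the erythroid, 0.32 for the foregut endoderm and 0.20 for the liver list, far above the preset 0.01. They were 0.10 for the endocardium and WNT lists, 0.02 for the FGF list and 0.007 for the second heart field list. For the cell cycle and atrioventricular canal lists they were below 0. Where the estimate lay below the preset, a higher correlation is not why the call was lost. With all arrays read as labelled 1 list passed, the ribosomal proteins. With arrays 1 and 2 only, 3 of the 9 passed, the erythroid, second heart field and liver lists.

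The arrays shared less of their pattern across dye orientations than within them. Across genes, which are not independent replicates, the log2 mutant over control ratios correlated at r = 0.45 between arrays 1 and 2 (Spearman 0.46) and at r = 0.41 between arrays 3 and 4 (Spearman 0.41). The 4 pairs with one array from each orientation gave r = 0.04, -0.28, -0.01 and -0.11 (Spearman 0.04, -0.22, -0.04 and -0.17). The mean over the 6 pairs was 0.085 with the signs of the authors' table and 0.203 with all arrays read as labelled.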

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

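The tests on the direction of the Hdac3 probe and on the erythroid list were chosen after the results were seen. So were those on both neighbouring lists and on other signs of the arrays. The reading of all arrays as labelled has the orientation of the fixed design, and only its use as an alternative was chosen after the data were seen. Of 99 named genes and lists, 6 had 1 array far from the other 3, against about 1 in 20 expected by chance. Lmnb1 was at 0.37 on array 1 and from 0.78 to 0.86 on the others, and Tnnc2 at 0.25 on array 1 and from 1.02 to 1.16 on the others. Spink1 was at -0.0699 on array 1 and from 0.976 to 1.098 on the others. Vil1 was at 0.96 on array 2 and from 0.30 to 0.40 on the others, and Rhag at -0.78 on array 2 and from -0.36 to -0.29 on the others. The cell cycle list had a median of -0.0290 on array 3 and of -0.08 on each of the others.

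More genes passed with Cy5 over Cy3 read one way on all arrays (108) than with the signs of the authors' table (0). Hdac3 had a mean log2 Cy5 over Cy3 of 0.77 on arrays 3 and 4 and lay below 0 on arrays 1 and 2, but wrong dye labels were considered because of this value, so it does not test them, and they would not by themselves give more genes in the one-way reading. In the fit with a dye term and the authors' signs, the dye coefficient passed for 153 genes higher and 36 lower in Cy5 (limma, adjusted p below 0.05). The mutant coefficient passed for 0. If the authors' signs are right, this is a dye effect shared by the arrays. If the labels are right, dye and genotype are not separated. A dye effect shared by the arrays therefore stays open as the cause. The second brightest probe had 16.4% of the called probe's ratio (median of 40 genes), but the measure was also low, at 32.0% (median of 27 genes), among the 108 genes of smallest p under the authors' signs, so it does not separate a dye effect from selection of extreme probes, and the correlation of probe GC content with Cy5 over Cy3 (Spearman -0.160) fell between the bounds set for it. All 8 sign patterns of the 4 arrays reach a count of 0 by definition, so this count tests nothing for the authors' signs, and the highest other count, 108, came from the pattern that follows the dye.

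Erythroid genes were lower in the mutant pools (median log2 ratio -0.24). Without array 2, the array of the largest shift, the median was -0.16, with -0.13 and -0.18 on arrays 3 and 4 but 0.00 on array 1. The bounds for this test were set after the array medians had been seen, so it does not decide whether 1 array made the shift. Different amounts of blood in the pools of a pair stay open: on array 2, 96.4% of the members lay below 0, but that array was picked for its large shift, so the share decides nothing. A reduced number of red cells in the mutant embryos stays open as well, untested.

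Second heart field and foregut endoderm genes were higher in the mutant pools (medians 0.18 and 0.17). A normalization effect on the second heart field list is argued against by its lowest median of 0.126 over the alternatives chosen before the data were examined. More tissue next to the heart in the mutant pools could account for both lists, whose medians were both above 0 on 3 of 4 arrays. On array 1 the 2 medians had opposite signs (0.17 and -0.07), which had been set down as the outcome against this explanation. The endoderm median lay within 2 of its standard errors (0.0447) of 0, but this allowance was added after that outcome was seen. The test was itself chosen after the results were seen, so it does not decide. With the authors' signs, lists of other tissues in or near the heart went both ways and did not pass. Their medians were -0.13 for the epicardium, -0.04 for the neural tube, 0.003 for the neural crest and 0.11 for somites. A change in the progenitors with loss of Hdac3 stays open as a hypothesis and was not tested. For the number of lists past the threshold, 1 of 8 sign patterns gave as many as the 9 of the authors' signs, with 6 as the highest of the others, and 8 patterns are too few for a share under 0.05.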

How the results depend on the processing

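The reading with all arrays as labelled has the orientation of the fixed design and became an alternative once arrays 3 and 4 were turned. The fits with a dye term and of replicates 1 and 2 only were chosen after seeing the data, and the other alternatives before. With the signs of the authors' table, 0 genes were higher and 0 lower under every such other setting run on 4 arrays, including the fit with no replicate block on 8 separate channels (0 and 0), and the means of Hdac3 stayed below 0. Leaving out each replicate gave 0 to 5 genes higher (5 without replicate 1), 0 to 0 lower, 6 to 11 gene lists past the threshold and a mean for Hdac3 of -0.68 to -0.38. With all arrays as labelled, 99 genes were higher, 9 lower and 1 list passed. In place of 9 lists, 0 passed with an estimated correlation and 0 with fry. With no replicate block 9 lists passed, 8 of them among the 9, with a dye term 7, all among the 9, and with replicates 1 and 2 only 8, of which 3 were among the 9. Of 18 settings chosen before that refitted the ratios, the erythroid, second heart field, liver and endocardium lists passed in 18, the cell cycle list in 17, the foregut endoderm list in 16, the WNT list in 13, the atrioventricular canal list in 12 and the FGF list in 9. The sample identity levels moved by less than their spread with Agilent processed signals, the setting tried for them, and the agreement between arrays did so under the 4 settings tried for it. Its mean r was 0.026 with median centring and 0.203 as labelled, against 0.085. The SD of 0.29 over the 6 pairs holds the gap between pairs within and across dye orientations, so it is a loose bound. Of the pluripotency and ribosomal genes, Tdgf1 (0.535), Lin28a (0.391) and Rps2 (-0.380) were followed as well. Tdgf1 was at 0.305 without replicate 3, and its other probes read 0.256 and 0.182. Rps2 was at -0.198 without replicate 4 and -0.580 without replicate 1, and its other probe read -0.248. Signs of the genes and lists with a mean or median over 4 arrays given here turned as follows, and the cause was not tested except where the alternative turns 2 arrays by construction. With all arrays as labelled: Hdac3 (0.213), Nkx2-5 (0.249), Tgfb1 (-0.0403), Igf2os (-0.0423), Kcna5 (-0.0332), Lmnb1 (-0.133), Pvalb (-0.0474), Tnnc2 (-0.190), Smoc2 (-0.0113), Sbk3 (-0.0957), Ly6h (-0.0325), Acyp2 (0.0377), Phox2a (0.129), Lrrc42 (0.0379), Epb42 (0.0210), Kat2b (0.156), Trib2 (0.206), Bhlhb9 (0.175), Ndrg4 (0.0447), Arhgap18 (0.127), Tbx2 (-0.162), Tbx3 (-0.183), Cdc25c (0.0626), Mcm4 (0.172), E2f2 (0.0215), Erg (-0.126), Cldn5 (-0.0227), Emcn (0.114), Fgf1 (0.164), Dusp6 (-0.351), Spink1 (-0.293), Krt18 (-0.273), Cldn7 (-0.120), Trim10 (0.0566), Fst (-0.272), Tbx1 (-0.00243), Fzd10 (-0.0617), Wnt2 (-0.275), Tcap (-0.301), Xirp1 (-0.140), Smpx (0.0213), Hey2 (0.320), Tbl1x (-0.104), Tdgf1 (-0.412), Lin28a (-0.0419), Rps2 (0.443), the atrioventricular canal list (-0.0759), the endocardium list (-0.0471), the FGF list (-0.0465), the foregut endoderm list (-0.126), the WNT list (-0.0604), the TGF-β list (-0.0521), the deacetylase list (-0.0643), the pluripotency list (0.000266), the ribosomal list (0.274) and the skeletal muscle list (-0.174). With median centring in place of loess: Nkx2-5 (0.0438), the cell cycle list (0.0406), the pluripotency list (0.0303), the ribosomal list (0.190) and the fatty acid oxidation list (0.00413), where the median of all genes moved to 0.0658 and of these only the ribosomal list lay above it. With array weights: Nkx2-5 (0.0480), the TGF-β list (-0.00658), the deacetylase list (-0.0236), the ribosomal list (0.151) and the skeletal muscle list (-0.0307). With replicates 1 and 2 only: Nkx2-5 (0.168), Rps2 (0.0628), the TGF-β list (-0.0872), the deacetylase list (-0.0322), the pluripotency list (0.00597), the ribosomal list (0.236) and the skeletal muscle list (-0.102). With Agilent processed signals: the cardiac factor list (-0.00188) and the pluripotency list (0.0661). With no background correction: the pluripotency list (0.0460) and the ribosomal list (0.00358). With the mean of a gene's probes: the pluripotency list (0.0324). With the authors' normalized table: the pluripotency list (0.0375) and the ribosomal list (0.00200). Among the genes and lists with a mean or median over 4 arrays given here, ranges over leaving out each replicate that crossed 0 were those of Nkx2-5 (-0.181 to 0.0884) and of the cardiac factor (-0.034 to 0.059), chamber (-0.022 to 0.042), deacetylase (-0.031 to 0.035), pluripotency (-0.025 to 0.0072), ribosomal (-0.11 to 0.11), sarcomere (-0.042 to 0.095) and sex-linked (-0.15 to 0.0047) lists. Signal over background limits what can be measured to the 25483 of 39429 probes that passed the filter.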

Other observations

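Among further gene groups that did not pass, Hox genes had a median log2 ratio of 0.04 (15 members, camera adjusted p = 0.114), and 4 passed adjusted over the list alone. Skeletal muscle and somite genes had a median of 0.11 (12 members, adjusted p = 0.0736), which was 0.0077 without replicate 4 and -0.174 with all arrays read as labelled, and 3 passed adjusted over the list alone. Epicardial genes had a median of -0.13 (17 members, adjusted p = 0.156; -0.0625 without replicate 2), germline genes -0.09 (16 members, adjusted p = 0.216; -0.0400 without replicate 1) and fatty acid oxidation genes -0.05 (32 members, adjusted p = 0.310; -0.0176 without replicate 1). For the pluripotency list the median and the camera test had opposite signs, and the list did not pass.

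Without replicate 1, 5 genes were higher at an adjusted p below 0.05. They are named here after their values were seen. Apart from Tnnc2 (log2 ratio 1.11), they were Prl2c5 (2.87), Prl3d2 (1.43), Prl3d1 (1.18), which encode placental prolactin-family hormones, and Gzme (1.57), a granzyme. On array 1 the ratios were -1.94 for Prl2c5, -1.52 for Prl3d2, -0.84 for Prl3d1 and -0.80 for Gzme.

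The sex-linked transcripts differed between the mutant and control pools of a pair, and not alike in every pair. On array 1, where both readings have the same sign, Xist was higher and Ddx3y and Eif2s3y lower in the mutant pool. Sex is therefore not separated from genotype in that pair. With all arrays read as labelled, Xist lay above 0 and Eif2s3y below 0 on every array, while Ddx3y lay above 0 on array 3. The values that follow have the authors' signs. Xist had log2 ratios of 1.04, 0.85, -0.26 and -0.28 on arrays 1 to 4, Ddx3y -2.05, -0.33, -0.32 and 0.45, and Eif2s3y -2.26, -0.46, 0.43 and 0.59.

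The ribosomal protein genes had a median Cy5 over Cy3 above 0 on every array. As labelled, this reads as 0.274 in mutant over control (camera adjusted p = 4.92e-18), so dye and genotype are not separated, and with the authors' signs the mutant over control median was 0.25 and 0.22 on arrays 1 and 2 and -0.28 and -0.33 on arrays 3 and 4. Rps2 was at 0.22, -0.09, -0.72 and -0.93 on the 4 arrays.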
